A study of Homo sapiens with 12 samples.

How the data were processed

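RNA was measured by sequencing in 12 libraries from human HEK293T cells, a line derived from embryonic kidney that is widely used for transfection. The labels give the line as HEK293T and the growth conditions name it HEK293. Cells carried a plasmid for the Halo tag alone (Control) or for the Halo tag fused to residues 196 to 346 of TNIP2 (called the TNIP2 fragment here), and each construct had an extract fraction (Input) and a fraction purified through the tag (Pulldown), giving 4 groups with 3 libraries in each. RNA came from 100 µl of extract or 90 µl of purified material, through a column kit, followed by removal of ribosomal RNA, per the labels' protocols. Nothing in the labels says that replicates came from separate transfections, so p-values measure the spread between these libraries, which may be technical. Columns were matched to groups by their letters: C, I and P match the labels, and the remaining letter was assigned to the TNIP2 fragment by elimination, since the series has no other construct.

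The authors deposited a table of normalized counts and a table of FPKM values, both by gene symbol, with 1 column per library. TopHat2 2.0.14, DESeq2 1.6.3 and the genome build hg19 are named per the submitters' processing notes; the read counter, its strand setting and the annotation are not given in the sources used here. The deposited normalized count is a score rather than a raw count: its values are whole numbers, yet the median-of-ratios factors of all 12 columns lay between 1.00 and 1.01, and a single constant per gene turned the deposited FPKM into it. Dividing by library factors and rounding to whole numbers is inferred from these values as a step of the authors, and counts below a few reads carry a rounding error. In the deposited FPKM table, low values of each library were whole multiples of a step, so whole reads and exonic length per gene were recovered; all of the 1690 to 6217 low values checked per library came out whole within 0.1 reads, and the search found 12 of 12 known steps on simulated data. Recovered depth was 20791296, 13793772 and 16331358 reads in Control Input, 3591136, 6404745 and 4037118 in Control Pulldown, 16759367, 14494624 and 8898497 in TNIP2 Input and 15288764, 29529590 and 10313212 in TNIP2 Pulldown. The deepest library held 8.22 times the reads of the shallowest, and 1 read was worth between 0.510 and 2.86 normalized counts, so low genes are measured least precisely in Control Pulldown.

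Of 25369 genes in the tables, 4492 were at 0 in every library, and 14627 with a normalized count of 10 or more in at least 3 libraries were tested. Values were taken as log2(normalized count + 1), which understates the change of low genes, and all 12 libraries were fitted together with a mean per group in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with trend and 8 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested, and genes were called at an adjusted p under 0.05. The 5 comparisons were Pulldown against Input for each construct, TNIP2 fragment against tag alone in each fraction, and the difference of enrichments, which subtracts the Pulldown-over-Input change of the tag alone from that of the TNIP2 fragment. A plan to use a count model was set aside because the deposited values are normalized. Fold changes come from the fitted log2 values, and group values are means ± SD of normalized counts with n = 3.

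Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison that have at least 3 members tested. The 30 lists were fixed before the data were examined, together with the comparisons, the tests and most alternatives. They were NF-kB targets and signalling components, replication-dependent histones, mitochondrially encoded genes, cytosolic and mitochondrial ribosomal proteins, box C/D and H/ACA snoRNAs, spliceosomal snRNAs, other small structured RNAs, snoRNA hosts, nucleus-retained long non-coding RNAs, microRNA hosts, microRNAs, numbered zinc fingers, endoplasmic reticulum chaperones, cytosolic heat shock genes, immediate early genes, interferon-stimulated genes, hnRNP and SR proteins, translation factors, oxidative phosphorylation, glycolysis, tubulin and actin, mitosis, DNA replication, cholesterol synthesis, and markers of blood, of fibroblasts and endothelium, and of epithelium. The list of mitochondrially encoded genes had 0 members in the tables, which left 29 lists tested. The spliceosomal snRNA list was drawn by symbol and also took in RNU86, a snoRNA gene. Its values are therefore not of spliceosomal snRNAs alone. Named genes are TNIP2, the 8 highest and 8 lowest log2 fold changes per comparison among called genes whose libraries do not overlap between groups and whose higher group averages 100 or more, passing over unnamed identifiers, and up to 4 members with the smallest p per list; genes outside this rule are named as chosen after their values were seen. Symbols are those of the deposited tables, of which 22463 are current symbols in the RefSeq table of GRCh38.p14; since the authors' build differs, that table served only for gene classes and for which genes neighbour each other, and no coordinates are given. Histone, tubulin and ribosomal protein genes have near-identical copies, small RNAs lie inside other genes, and without a known strand setting antisense genes share reads with their partners, so values of single members are uncertain. PLCG2 is uncertain as well, because the table places a 7SK pseudogene, RN7SKP176, within it.

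The gene and list tests were checked on simulated libraries with 200 genes changed by known folds and a further list of 30 genes shifted together, among 14450 tested. In the simulated difference of enrichments, 0% of genes changed 1.5-fold, 32.0% of those changed 2-fold, 68.0% of those changed 3-fold and 82.0% of those changed 4-fold were called, and 4 of 14220 unchanged genes were called. In the simulated TNIP2 Pulldown against TNIP2 Input the shares were 22.0%, 66.0%, 88.0% and 98.0%, with 5 of 14220 unchanged genes called. The list of 30 passed camera in the simulated difference of enrichments (adjusted p = 1.7e-09), and 0 of 100 random lists did. The simulation changed few genes, of higher mean counts, and gave each gene the same spread in all groups. The real difference of enrichments called 42.8% of genes. Deviations had SDs from 0.10 (Control Input replicate 2) to 0.39 (TNIP2 Pulldown replicate 3). These shares of recovered and false calls therefore do not carry over. Whether replicate numbers pair libraries was checked by correlating deviations from group means across 10469 genes. Input and Pulldown of the TNIP2 fragment with the same number gave r = 0.40, 0.50 and 0.49, all above 0.1, and the design text has both fractions drawn from the same extract, so these were taken as pairs. The same check for the tag alone gave 0.08, 0.27 and 0.08, and numbers were not taken to pair libraries there or across constructs. The main fits held group means only and did not use the pairs. In the gene and list tests, pairs entered only through the replicate blocks among the alternatives. Alternatives were the pseudocount, the filter, 3 other scalings, the FPKM table, robust moderation, fits on only the libraries compared, replicate blocks, library weights and leaving out each library; voom on recovered reads, thinning to the shallowest library and leaving out both TNIP2 libraries numbered 3 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.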

Results

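Total RNA from HEK293T extracts and RNA carried through a Halo-tag purification were compared for cells expressing the Halo tag alone or the tag fused to residues 196 to 346 of TNIP2, an adaptor protein known to bind ubiquitin and to restrain NF-kB signalling. Each of the 4 groups had 3 libraries. Recovered depth was 3591136 to 6404745 reads in Control Pulldown, 13793772 to 20791296 in Control Input, 8898497 to 16759367 in TNIP2 Input and 10313212 to 29529590 in TNIP2 Pulldown. On the first principal component, which held 66.7% of the variance, the 3 TNIP2 Pulldown libraries had scores from 94.9 to 112. The Control Pulldown and all Input libraries, 9 in total, had scores from -37.5 to -29.3.

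The TNIP2 transcript was examined first, since the transfected plasmid carries part of its coding sequence. Its normalized counts were 278, 304 and 272 in the 3 Control Input libraries and 16750, 13318 and 46568 in TNIP2 Input, a log2 fold change of 6.26 (SE 0.57, adjusted p = 2.6e-04). They were 51905, 69806 and 193013 in TNIP2 Pulldown and 1472, 309 and 391 in Control Pulldown, a log2 fold change of 7.30 (SE 0.57, adjusted p = 1.0e-07). All 6 libraries labelled with the TNIP2 fragment lay above all 6 tag-only libraries. Within the TNIP2 fragment, Pulldown exceeded Input by 2.02 (SE 0.57, adjusted p = 0.0068), and the same-numbered libraries gave ratios of 3.10, 5.24 and 4.14. This call ended under quantile normalization (log2 fold change 1.10, adjusted p = 0.15) and under centring on ribosomal protein genes (1.55, adjusted p = 0.056), with 9.0e-05 to 0.15 over all alternatives. With the tag alone the ratios were 5.29, 1.02 and 1.44. The difference of enrichments for TNIP2 did not pass the test, at 1.04 (SE 0.80, adjusted p = 0.32), and depended on single libraries. It was 1.74 without Control Pulldown replicate 1, 0.61 without Control Pulldown replicate 2, 0.69 without TNIP2 Input replicate 2, 1.59 without TNIP2 Input replicate 3 and 0.48 without TNIP2 Pulldown replicate 3. Among other settings it was 0.07 under quantile normalization and 0.46 under centring on ribosomal protein genes, with 0.051 to 0.96 over all alternatives.

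**Figure D1:**
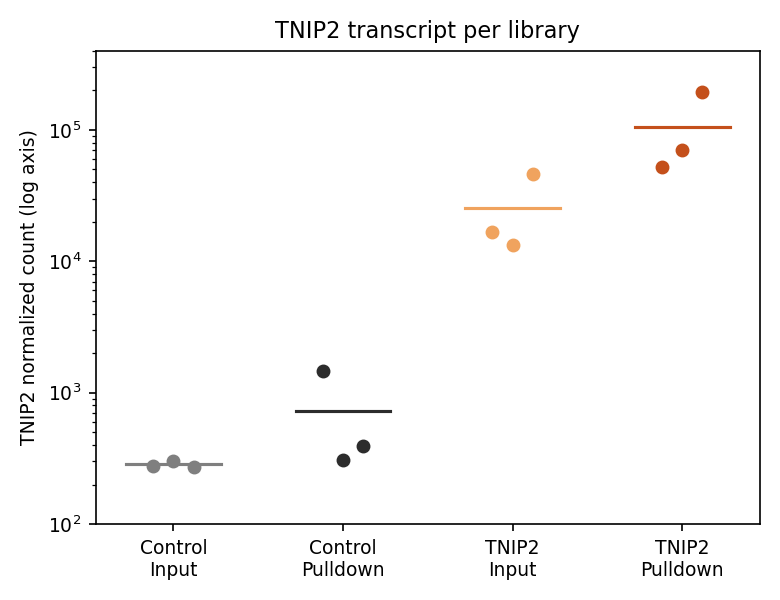
Normalized counts of the TNIP2 transcript in each of 12 libraries on a log axis; points are libraries and horizontal lines are group means (n = 3). The 6 libraries of the TNIP2 fragment sit between 13318 and 193013, and the 6 tag-only libraries between 272 and 1472.

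Control Pulldown against Control Input asked which RNAs the tag and resin carry by themselves. With the tag alone, histone and small structured RNAs were lower in purified material than in extract. RMRP, the RNA of RNase MRP, fell from 93195 ± 26215 to 13210 ± 1913 normalized counts (SD, n = 3), a log2 fold change of -2.79 (SE 0.32, adjusted p = 8.0e-04). SCARNA10, a small Cajal body RNA, fell from 279 ± 135 to 13.3 ± 6.43, a log2 fold change of -4.31 (SE 0.46, adjusted p = 5.9e-04), and RNVU1-19, a variant U1 spliceosomal RNA, had -4.17 (SE 0.60, adjusted p = 0.0067). SNORA48 had a log2 fold change of -3.70, and the histone genes HIST1H4J, HIST1H4D and HIST1H4B had -2.89, -2.70 and -1.94. The call of HIST1H4B ended without Control Pulldown replicate 1 (adjusted p = 0.059, 1.1e-06 to 0.059 over all alternatives). PLCG2 fell by 2.87 on the log2 scale, but a 7SK pseudogene lies within the gene, so this value is uncertain.

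In limma, 20 genes were lower and 0 were higher, and 342 had an unadjusted p under 0.05; voom on recovered reads gave 18 lower and 1 higher. Of the 20 genes, 9 were histones, 7 were H/ACA snoRNAs or scaRNAs, and the others were SNORD97, RNVU1-19, RMRP and PLCG2, of which SNORD97 (log2 fold change -3.43, outside the naming rule) was chosen after its values were seen. Among 46 histone genes tested the median log2 fold change was -1.03, with 9 lower over all genes and 38 lower when adjusted over the list alone. The 66 H/ACA and scaRNA genes had a median of -0.61, with 7 lower over all genes and 20 adjusted over the list alone. Relative to the Control Input mean, their median was -0.92, -0.41 and -0.41 in Control Pulldown replicates 1, 2 and 3, and without replicate 1 the median relative to other genes was -0.36 in place of -0.60. Medians were -1.65 for the 6 genes of the spliceosomal snRNA list, which include the snoRNA gene RNU86, with 1 lower over all genes and 4 adjusted over the list alone. For 5 other small structured RNA genes the median was -1.82, with 1 and 5. All 4 lists passed camera at the preset correlation and with an estimated correlation (adjusted p = 0.0064, 0.0039, 0.0066 and 0.0039). Box C/D snoRNAs (median -0.19), oxidative phosphorylation genes (-0.18) and cytosolic ribosomal protein genes (-0.14) passed only at the preset correlation, with adjusted p = 0.69, 0.69 and 0.72 with an estimated correlation. The box C/D median relative to other genes was -0.18, but -0.35 without Control Pulldown replicate 3 and -0.10 without Control Input replicate 3. The direction of the test of the ribosomal protein list turned under quantile normalization, and its call ended with no filter (adjusted p = 0.12), without Control Input replicate 1 (adjusted p = 0.059) or Control Pulldown replicate 1 (adjusted p = 0.084), with 1.3e-06 to 0.92 over all alternatives. The number of lower genes was 12 without Control Input replicate 1, 12 without Control Input replicate 2, 12 without Control Pulldown replicate 1 and 31 without TNIP2 Pulldown replicate 1. It was 40 without both TNIP2 libraries numbered 3, and 44, with 4 higher, in a fit on only these 6 libraries. Library weights gave 111 lower and 25 higher, in an estimate of weights that did not converge.

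TNIP2 Pulldown against TNIP2 Input asked which RNAs the purified fragment carried relative to its own extract. CMTM8 rose from 127 ± 13.0 to 1820 ± 775 normalized counts (SD, n = 3), a log2 fold change of 3.73 (SE 0.27, adjusted p = 6.6e-08), and MT2A, a metallothionein that binds metal ions, rose from 116 ± 24.0 to 1547 ± 415, 3.70 on the log2 scale. ID2, an inhibitor of helix-loop-helix transcription factors, rose from 1614 ± 327 to 19508 ± 3631, a log2 fold change of 3.60 (SE 0.17, adjusted p = 5.0e-09). PLEKHA5, TSHZ1, BHLHE40, FAM135A and SERTAD4-AS1 had log2 fold changes of 3.59, 3.59, 3.55, 3.55 and 3.50. RMRP had the lowest value of all genes tested, from 119913 ± 40095 to 1529.7 ± 653, a log2 fold change of -6.36 (SE 0.32, adjusted p = 6.7e-09), followed by RPPH1, the RNA of RNase P, at -5.89 (SE 0.37, adjusted p = 2.1e-08). RNVU1-19, PLCG2 (uncertain, as above), SCARNA10, HIST1H4H, HIST1H3A and HIST1H4C had log2 fold changes of -5.61, -4.55, -4.20, -4.17, -4.14 and -4.12.

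Of 29 lists, 10 passed camera at the preset correlation. Histones had 40 of 46 members lower, 0 higher and a median of -2.11. Camera gave adjusted p = 3.4e-14 at the preset correlation and adjusted p = 0.39 with an estimated correlation. Of 30 mitosis genes, 20 were higher and 4 lower (median 1.03), with CCNB1, KIF20A and UBE2C at 2.63, 2.47 and 2.13. Camera gave adjusted p = 9.4e-04, and adjusted p = 0.39 with an estimated correlation. Immediate early genes had 19 of 27 higher and 2 lower (median 0.87; adjusted p = 0.0038, and adjusted p = 0.39 with an estimated correlation), among them JUN at 2.73 and JUNB at 1.97. Cholesterol synthesis genes had 16 of 20 lower and 3 higher (median -0.98; adjusted p = 0.0015, and adjusted p = 0.39 with an estimated correlation). H/ACA and scaRNA genes had 38 of 66 lower and 9 higher (median -1.22; adjusted p = 0.0015, and adjusted p = 0.39 with an estimated correlation), and other small structured RNAs had 4 of 5 lower (median -3.88; adjusted p = 0.0015, and adjusted p = 0.39 with an estimated correlation). Glycolysis genes had 9 of 18 lower and 0 higher (adjusted p = 0.024, and adjusted p = 0.68 with an estimated correlation), with TPI1 at -2.22. The preset call of glycolysis ended without TNIP2 Input replicate 2 (adjusted p = 0.063) or TNIP2 Pulldown replicate 2 (adjusted p = 0.053), with 9.1e-04 to 0.063 over all alternatives, and that of H/ACA genes under a stricter filter (adjusted p = 0.21, 1.5e-04 to 0.21 over all alternatives). Oxidative phosphorylation genes had 43 of 76 lower and 20 higher (median -0.70, adjusted p = 0.012, and adjusted p = 0.96 with an estimated correlation), with COX5A at -2.62 and ATP5I at 2.95. Without both TNIP2 libraries numbered 3 the preset test of this list gave adjusted p = 0.087 (2.1e-04 to 0.087 over all alternatives). Mitochondrial ribosomal protein genes had 42 of 76 lower and 17 higher (adjusted p = 0.0045, and adjusted p = 0.78 with an estimated correlation). Cytosolic ribosomal protein genes had 40 of 80 higher and 16 lower (adjusted p = 0.013, and adjusted p = 0.96 with an estimated correlation), but the direction of this test turned under quantile normalization. Without TNIP2 Pulldown replicate 3 its median relative to other genes was 0.77 in place of 0.48. Adjusted over the list alone, 41 histones, 38 H/ACA genes and 16 cholesterol genes were lower, and 20 mitosis genes and 19 immediate early genes were higher. In limma 4358 genes were higher and 4145 lower, of which 2744 and 2461 changed at least 2-fold. These calls made up 58.1% of the 14627 genes tested, so members called in both directions are not particular to a list. Centring on ribosomal protein genes gave 2437 higher and 6033 lower, a share of higher calls of 28.8% in place of 51.3%.

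**Figure D2:**
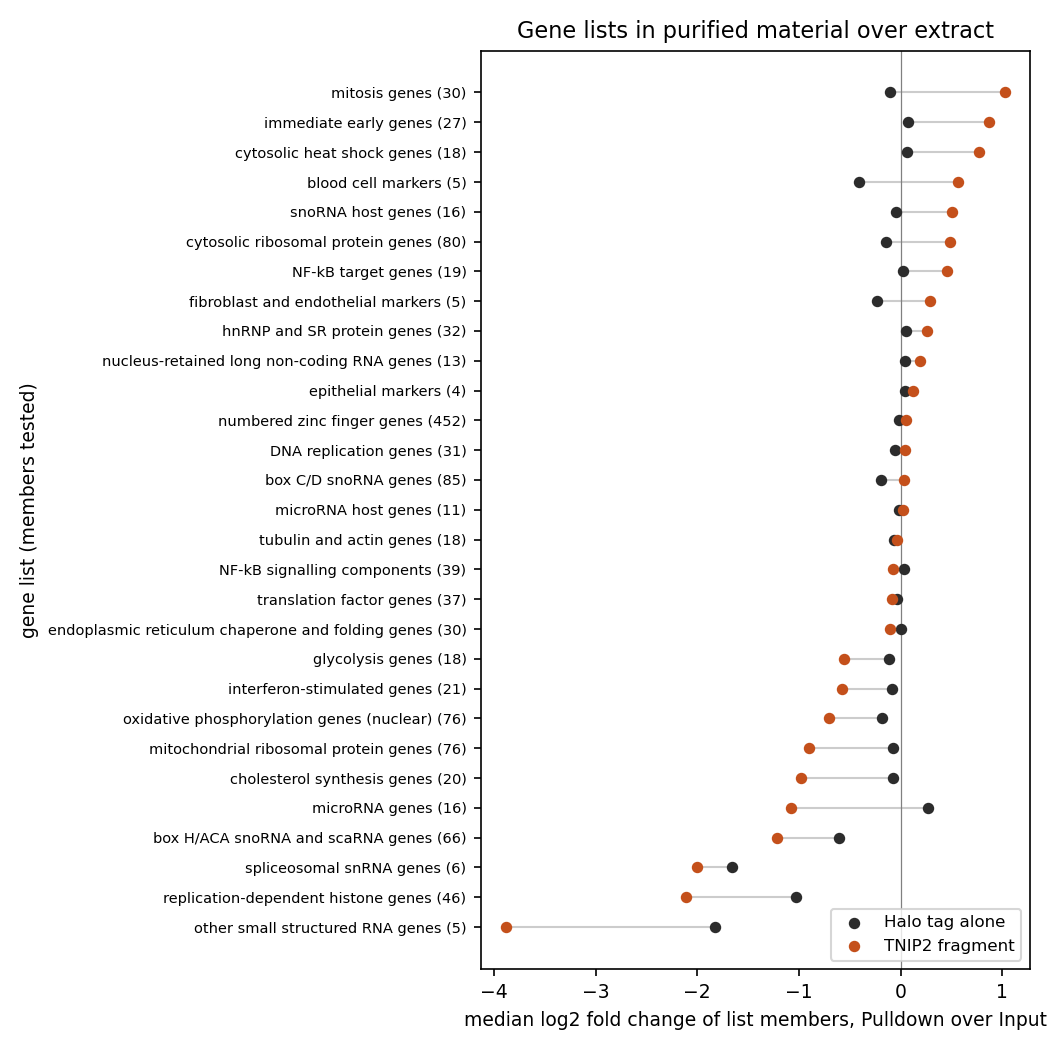
Median log2 fold change of Pulldown over Input for each of 29 gene lists, with the tag alone in dark grey and the TNIP2 fragment in orange-brown; numbers in brackets count the members tested. Histone genes sit at -1.03 with the tag alone and -2.11 with the TNIP2 fragment, while mitosis genes sit at -0.11 and 1.03.

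TNIP2 Pulldown against Control Pulldown compared the purified RNA of both constructs directly. GATA2, a transcription factor of blood and endothelial development, had 187 ± 10.5 and 3344 ± 358 normalized counts in Control and TNIP2 Pulldown (SD, n = 3), a log2 fold change of 4.15 (SE 0.25, adjusted p = 1.6e-08). MT2A, SNORD30, CMTM8, ZSCAN5A and BCL2L12 had log2 fold changes of 4.04, 3.96, 3.88, 3.84 and 3.75. HSPA6, an inducible heat shock gene, had 3.71 (SE 1.10, adjusted p = 0.0094), but its counts in TNIP2 Pulldown were 43, 39 and 608. The call ended without replicate 3 of that group (log2 fold change 2.42, adjusted p = 0.056), in voom (adjusted p = 0.087) and after thinning (adjusted p = 0.069), with 0.0018 to 0.087 over all alternatives. HRSP12 fell from 571 ± 21.1 to 31.3 ± 7.23, a log2 fold change of -4.17 (SE 0.19, adjusted p = 2.7e-09). SELM, RPPH1, SEC11C, DDT, TMEM256, PDZD11 and SCARNA2 had log2 fold changes of -3.84, -3.73, -3.40, -3.36, -3.33, -3.32 and -3.25. Immediate early genes had 19 of 27 higher and 0 lower (adjusted p = 3.7e-04, and adjusted p = 0.61 with an estimated correlation), mitosis genes 18 of 30 higher and 4 lower (adjusted p = 0.0018, and adjusted p = 0.61 with an estimated correlation), and histones 34 of 46 lower and 2 higher (adjusted p = 4.7e-06, and adjusted p = 0.85 with an estimated correlation). Cholesterol synthesis genes had 16 of 20 lower and 2 higher (adjusted p = 0.0024, and adjusted p = 0.61 with an estimated correlation). The preset call of mitosis genes ended under quantile normalization (adjusted p = 0.077, 2.9e-04 to 0.077 over all alternatives). NF-kB targets had 8 of 19 higher and 3 lower and did not pass camera (adjusted p = 0.11), except with no filter (adjusted p = 0.045, 0.045 to 0.16 over all alternatives). Mitochondrial ribosomal protein, glycolysis, oxidative phosphorylation and other small structured RNA genes also passed at the preset correlation with medians of -1.02, -0.58, -0.59 and -2.79, and had adjusted p = 0.92, 0.85, 0.92 and 0.61 with an estimated correlation. The preset call of oxidative phosphorylation ended without Control Pulldown replicate 2, TNIP2 Pulldown replicate 2 or TNIP2 Pulldown replicate 3 (adjusted p = 0.056, 0.066 and 0.14, 0.0013 to 0.17 over all alternatives). That of other small structured RNAs ended with no filter, on FPKM and with centring on ribosomal protein genes (adjusted p = 0.050, 0.051 and 0.071, 0.012 to 0.071 over all alternatives). In limma 4481 genes were higher and 4201 lower, of which 2890 and 2515 changed at least 2-fold. These calls made up 59.4% of the genes tested. Centring on ribosomal protein genes gave 2966 higher and 5340 lower.

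TNIP2 Input against Control Input asked whether total RNA differed between the transfected cells. TNIP2 was the only gene called in limma: 1 gene was higher and 0 lower, and 104 had an unadjusted p under 0.05; voom on recovered reads gave 1 higher and 0 lower. Of the lists, immediate early genes stood higher as a set (27 tested, median 0.35, adjusted p = 2.1e-13). The list also passed narrowly with an estimated correlation (adjusted p = 0.046), a test not repeated under the alternatives. Of its members 0 were called, over all genes or adjusted over the list alone. BTG2, FOSL1, FOSB and EGR2 had the smallest p in the list, with log2 fold changes of 0.51 (SE 0.17), 1.66 (SE 0.66), 1.12 (SE 0.51) and 1.08 (SE 0.51), none of which passed adjustment. Relative to the Control Input mean, the list's median was 0.20, 0.26 and 0.51 in TNIP2 Input replicates 1, 2 and 3. In Control Input replicates 1, 2 and 3 it was -0.06, 0.04 and 0.15. TNIP2 Input replicate 3 lay apart from the other Input libraries on the second principal component. Cytosolic heat shock genes had a median of 0.24 (adjusted p = 2.1e-05, and adjusted p = 0.38 with an estimated correlation), and their medians per library were 0.14, 0.06 and 0.29. Without TNIP2 Input replicate 3 their median relative to other genes was 0.11 in place of 0.25. At the preset correlation 11 lists were called, and 5 without Control Input replicate 1. Cytosolic ribosomal protein genes had a lower median (-0.20, adjusted p = 2.1e-13, 2.1e-19 to 0.078 over all alternatives, and adjusted p = 0.49 with an estimated correlation), and their call ended under quantile normalization. Of the other 8 lists, translation factor genes had a median of -0.09 (adjusted p = 0.11 with an estimated correlation), but the preset call ended under quantile normalization, centring on ribosomal protein genes and library weights (6.0e-04 to 0.15 over all alternatives), and without TNIP2 Input replicate 3 the median relative to other genes was -0.14 in place of -0.08. The preset calls of the last 7 lists ended with single libraries left out, and none of these passed with an estimated correlation. Medians were -0.42 for 5 fibroblast and endothelial markers, 0.14 for box C/D snoRNAs and 0.34 for other small structured RNAs (adjusted p = 0.38, 0.78 and 0.38 with an estimated correlation). Relative to other genes these became -0.21 without Control Input replicate 1 (adjusted p = 0.26), 0.03 without TNIP2 Input replicate 3 (adjusted p = 0.64) and 0.11 without TNIP2 Input replicate 3 (adjusted p = 0.33). Oxidative phosphorylation, glycolysis, hnRNP and SR protein and mitosis genes had medians of -0.10, -0.09, 0.05 and -0.09 (adjusted p = 0.78, 0.74, 0.74 and 0.74 with an estimated correlation). Relative to other genes they became 0.00 without TNIP2 Input replicate 2 (adjusted p = 0.90), 0.01 without TNIP2 Input replicate 3 (adjusted p = 0.91), 0.01 without Control Input replicate 1 (adjusted p = 0.69) and -0.01 without TNIP2 Input replicate 2 (adjusted p = 0.63). Each of the 6 Input libraries, Control Pulldown replicate 3 and each TNIP2 Pulldown library ended the call of at least 1 of the 7 when left out, and Control Input replicate 1 ended 6. Library weights raised the count to 1866 higher and 1755 lower, in an estimate of weights that did not converge.

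The difference of enrichments, the main comparison, asked which RNAs were carried by the TNIP2 fragment beyond what the tag alone carried. MT2A went from 116 to 1547 normalized counts with the TNIP2 fragment and from 115 to 92.7 with the tag alone, a difference of 4.04 (SE 0.34, adjusted p = 1.8e-06) on the log2 scale. CMTM8 had a difference of 3.76 (SE 0.38, adjusted p = 5.8e-06) and ID2 of 3.71 (SE 0.24, adjusted p = 5.0e-07). RPS24, a protein of the small ribosomal subunit, went from 14692 ± 581 to 172663 ± 79978 with the TNIP2 fragment and from 18099 ± 1093 to 15439.7 ± 732 with the tag alone (SD, n = 3), a difference of 3.65 (SE 0.39, adjusted p = 9.0e-06). AUTS2 and FAM150A had differences of 3.69 and 3.63. The snoRNAs SNORD30 and SNORA63 had 3.74 and 3.61; SNORA63 was lower in Control Pulldown (-2.32) and higher in TNIP2 Pulldown (1.29) than in the Inputs, the first call of which ended in voom (adjusted p = 0.068). RPPH1 had a difference of -4.07 (SE 0.52, adjusted p = 3.5e-05), and RMRP had -3.57. HRSP12, SELM (a selenoprotein), BANF1 (a chromatin-binding protein of the nuclear envelope), SEC11C (a subunit of the signal peptidase), SCARNA2 and DDT (a homolog of the cytokine MIF) had differences of -3.91, -3.88, -3.51, -3.43, -3.41 and -3.39. In limma, 3301 genes had a higher and 2960 a lower difference, of which 2564 and 2161 were at least 2-fold. With libraries centred on ribosomal protein genes the counts were 1490 and 4952, a share of higher calls of 23.1% in place of 52.7%, with the median of all genes at -0.56 in place of 0.02. Of the 3301 and 2960 genes, 3238 and 2927 were also called the same way in TNIP2 Pulldown against TNIP2 Input and against Control Pulldown. All 3 comparisons use the same TNIP2 Pulldown libraries. Genes and lists that recur in them are therefore not separate support.

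Of 30 mitosis genes, which drive cell division, 16 had a higher difference and 2 a lower one (18 and 2 adjusted over the list alone), with a median of 1.01. CCNB1, the cyclin of mitotic entry, went from 2151 ± 427 to 13170.3 ± 845 with the TNIP2 fragment and had a difference of 2.87 (SE 0.22, adjusted p = 1.2e-06); KIF20A, UBE2C and PTTG1 had differences of 2.60, 2.36 and 1.95. Camera gave adjusted p = 2.9e-04 for this list at the preset correlation and adjusted p = 0.63 with an estimated correlation. Of 27 immediate early genes, which respond within minutes to stimuli, 12 had a higher difference and 0 a lower one (15 and 2 adjusted over the list alone; median 0.89). JUN, JUNB, MYC and IER5 had differences of 2.52, 2.03, 3.06 and 1.00, and the call of IER5 ended under centring on ribosomal protein genes (adjusted p = 0.16). This list gave adjusted p = 0.012, and adjusted p = 0.63 with an estimated correlation. Without TNIP2 Pulldown replicate 3 the first was 0.058 (0.0048 to 0.058 over all alternatives). NF-kB target genes, induced by the pathway that TNIP2 is known to restrain, had 6 of 19 members higher and 1 lower (5 and 0 adjusted over the list alone, median 0.41), and the list did not pass camera (adjusted p = 0.18). Its median relative to other genes was 0.39, and 0.24 to 0.49 with single libraries left out. These values set purified RNA against extract and do not measure activity of the pathway. In TNIP2 Input against Control Input, which compares total RNA, the list was not called. There its median relative to other genes was 0.09, and camera gave adjusted p = 0.10 to 0.67 over all alternatives. NFKBIA, the inhibitor of NF-kB that the pathway itself induces, went from 239.7 ± 10.8 to 1825 ± 570.0 with the TNIP2 fragment and from 248 ± 32.1 to 200.3 ± 45.5 with the tag alone (SD, n = 3), a difference of 3.20 (SE 0.32, adjusted p = 5.6e-06). TNFAIP3, the deubiquitinase A20, NFKB1 and IER3 had differences of 2.23, 1.63 and 1.76. NF-kB signalling components had 6 of 39 higher and 5 lower (6 and 4 adjusted over the list alone; adjusted p = 0.92), with TRAF3 at 1.55, MAP3K8 at 2.00 and TNFRSF1A at -1.44. Without both TNIP2 libraries numbered 3, which lay apart from the other 10 on the second principal component, 4235 genes had a higher and 3865 a lower difference.

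Histone genes had 23 of 46 members with a lower difference and 0 with a higher one, the same counts adjusted over the list alone, with a median of -0.90 (adjusted p = 1.5e-05, and adjusted p = 0.92 with an estimated correlation). HIST1H4H, HIST1H3F, HIST1H3H and HIST1H3A had differences of -2.36, -2.68, -2.55 and -2.73. Other small structured RNAs had 4 of 5 lower and 0 higher, the same adjusted over the list alone (median -3.06; adjusted p = 0.011, and adjusted p = 0.63 with an estimated correlation); TERC, the telomerase RNA, went from 1222 ± 253 to 80.7 ± 2.52 with the TNIP2 fragment and from 994 ± 94.9 to 572 ± 124 with the tag alone (SD, n = 3), a difference of -3.06 (SE 0.27, adjusted p = 2.6e-06). With libraries centred on ribosomal protein genes the test of this list gave adjusted p = 0.064 (0.0043 to 0.064 over all alternatives). Cholesterol synthesis genes had 11 of 20 lower and 1 higher (12 and 2 adjusted over the list alone; median -0.96; adjusted p = 0.0047, and adjusted p = 0.63 with an estimated correlation), with CYP51A1 at -2.32 and IDI1 at -1.09. Both ribosomal protein families held members called in each direction, as did all genes tested, of which 42.8% were called. Cytosolic ribosomal protein genes had 39 of 80 higher and 14 lower (42 and 15 adjusted over the list alone; median 0.63; adjusted p = 0.010, and adjusted p = 0.92 with an estimated correlation), with RPS25 and RPL10A at 3.51 and 2.53 and RPL30 at -2.28, but under quantile normalization the list median relative to other genes was -0.19 (adjusted p = 0.32, 1.1e-04 to 0.32 over all alternatives). Mitochondrial ribosomal protein genes had 40 of 76 lower and 15 higher, the same adjusted over the list alone (median -0.83; adjusted p = 0.010, and adjusted p = 0.92 with an estimated correlation); MRPL34 and MRPS28 had differences of 3.55 and 3.45, and MRPS25 and MRPL55 of -2.41 and -2.31. Without TNIP2 Input replicate 3 this list gave adjusted p = 0.054 at the preset correlation (0.0020 to 0.054 over all alternatives).

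The Pulldown-over-Input changes of both constructs, which share no library, were set against each other across genes, which are not independent replicates. Their log2 fold changes had Pearson r = 0.060 and Spearman rho = 0.0265 over 14627 genes, and their SDs were 1.11 for the TNIP2 fragment and 0.31 for the tag alone. Of the 20 genes lower in Control Pulldown, 18 were also lower in TNIP2 Pulldown, where 5.67 would overlap for independent lists. The remaining 2 were SNORA63 and SCARNA22, the second of which had -0.89 with the TNIP2 fragment and was chosen after its values were seen. The number lower with both constructs was 11 without Control Input replicate 1, 11 without Control Input replicate 2, 11 without Control Pulldown replicate 1 and 30 without TNIP2 Pulldown replicate 1. The correlation stayed between 0.0366 and 0.0758 when single libraries were left out.

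**Figure D3:**
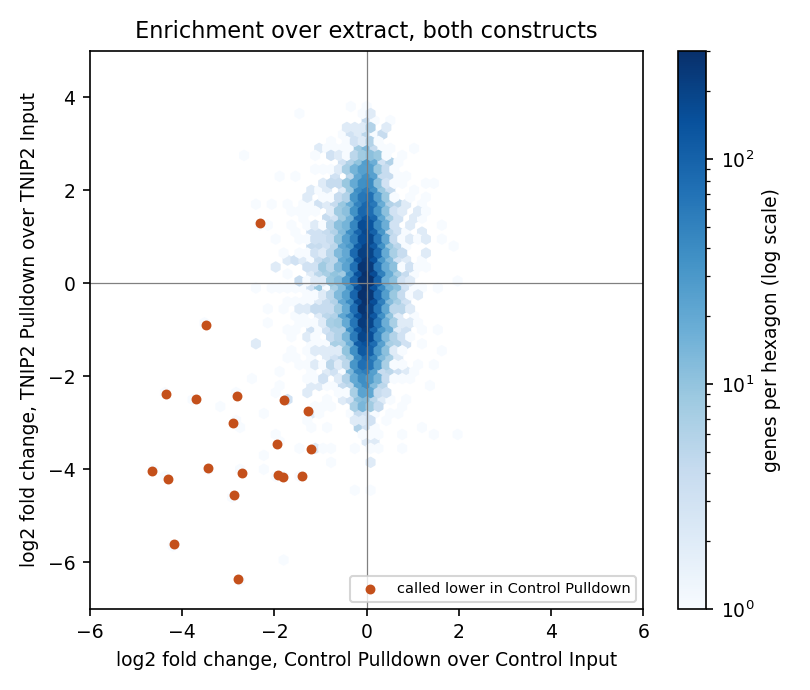
Log2 fold change of Pulldown over Input for 14627 genes, with the tag alone on the horizontal axis and the TNIP2 fragment on the vertical axis; hexagon shade gives the number of genes on a log scale, and points mark the 20 genes called lower in Control Pulldown. The cloud is wide vertically (SD 1.11) and narrow horizontally (SD 0.31), and 18 of the 20 marked genes were also called lower with the TNIP2 fragment.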

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

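Tests of depth, scaling, short transcripts, nuclear RNA and carry-over were chosen after the results they weigh were seen, and those of length and of other groupings of the libraries before. The tests of scaling and of nuclear RNA were first run in another form, on the number of calls and on the list with its cytoplasmic members, and these forms were replaced after their results were seen. The test of the difference of enrichments singled out 3301 genes as higher and 2960 as lower, that is, genes whose change on purification differed between the constructs. It singled out 7 lists, with median differences of 1.01 for mitosis genes, 0.89 for immediate early genes, 0.63 for cytosolic ribosomal protein genes, -0.90 for histones, -0.83 for mitochondrial ribosomal protein genes, -0.96 for cholesterol synthesis genes and -3.06 for other small structured RNAs; none of these passed with an estimated correlation, and the ribosomal protein list turned under quantile normalization. Among named genes it gave differences of 4.04 for MT2A, 3.76 for CMTM8, 3.74 for SNORD30, 3.71 for ID2, 3.69 for AUTS2, 3.65 for RPS24, 3.63 for FAM150A and 3.61 for SNORA63. On the lower side it gave -4.07 for RPPH1, -3.91 for HRSP12, -3.88 for SELM, -3.57 for RMRP, -3.51 for BANF1, -3.43 for SEC11C, -3.41 for SCARNA2 and -3.39 for DDT.

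Transcripts of 6261 genes differed in enrichment between the TNIP2 fragment and the tag alone. Lower depth of Control Pulldown would lose most calls once depth is equal, yet 84.9% of the 6261 called genes were called the same way with every library thinned to the shallowest. A bias on transcript length would lose them once the trend is removed, yet 89.5% were called the same way without it. Scaling stays open in part: under centring on ribosomal protein genes, the lowest of 3 other scalings, 71.1% were called the same way and 33 genes changed sign. This centring shifts all genes of a library alike and moved the median of all genes from 0.02 to -0.56. Lost calls and changed signs follow from that shift. The list used for it was itself called in this comparison (median 0.63), so the share cannot tell which scaling holds. The amount of RNA in each purification and effects of handling were not measured, and these and an effect of the construct itself stay open and untested.

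Histone and small structured RNA genes were lower in purified material even with the tag alone. Loss of short transcripts was weighed with genes outside the lists matched in length to the histones, whose median log2 fold change was -0.0562 against -1.03 for the histones, which argues against it for histones. For H/ACA snoRNAs it stays open: box C/D snoRNAs, which are shorter, lay above them by 0.41 with a standard error of 0.21, too close to 2 standard errors to decide. Loss of nuclear RNA would lower nucleus-retained long non-coding RNAs. From that list LINC00657 and OIP5-AS1, which are known as cytoplasmic, were left out. The median of the 11 genes left was 0.0104 with a standard error of 0.12, and 1 lay at or below -0.5. This argues against a general loss of nuclear RNA, for long transcripts. The list holds no small nuclear RNAs, so a loss of these alone was not tested by it. Histone mRNAs and the small RNAs that fell share the lack of a poly(A) tail, and whether that relates to their loss was not tested. Box C/D snoRNAs lack this tail as well, and their median with the tag alone was -0.19.

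TNIP2 reads were higher in Control Pulldown replicate 1 than in replicates 2 and 3, an excess of 1122 normalized counts. Carry-over of TNIP2 Pulldown replicate 1 or 2 would shift 426 genes of higher difference against 825 of lower difference by 0.147 or 0.130 on the log2 scale, and the shift seen was 0.00332, within the -0.0215 to 0.010 of the other 2 libraries, which argues against these sources. Carry-over from TNIP2 Pulldown replicate 3 would give 0.0332. That is above the shift seen, but not far beyond the spread of the other 2 libraries, so this source was not decided. Carry-over from a TNIP2 Input library would give 0.000991 to 0.00911, shifts too small to be seen. These sources cannot be told apart from an excess of another origin. No biological explanation was tested.

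Other groupings of the libraries were counted for each comparison. In comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05, and in each of them 1 split, the real one, gave as many genes: real and highest other counts were 8503 and 1 for TNIP2 Pulldown against TNIP2 Input, 20 and 0 for Control Pulldown against Control Input, 8682 and 0 for TNIP2 Pulldown against Control Pulldown, and 1 and 0 for TNIP2 Input against Control Input. For the difference of enrichments, construct labels were reassigned within Inputs and within Pulldowns, with 100 of 200 splits drawn, and 10 of the 100, the real one included, gave at least the real 6261 genes, up to 7171. All 10 kept the construct labels of the Pulldown libraries and the 9 others than the real one differed in those of the Inputs, between which 1 gene was called, so a count near the real one was to be expected of them and the tally of 10 says nothing on chance. The highest count among the 90 splits that mixed the Pulldown labels was 0. Mixing puts the difference between the Pulldowns into the spread, so a low count was to be expected of these as well. Among the 90 were the 3 other drawn splits that kept same-numbered Input and Pulldown libraries of both constructs together. Their counts of 0 genes are therefore no separate evidence.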

How the results depend on the processing

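Leaving out both TNIP2 libraries numbered 3, voom and thinning were chosen after the data were seen. The genes and list members counted next were picked for extreme values or small p in these data. High shares kept were therefore to be expected of them. Of all 6261 genes called in the difference of enrichments, 4450 were called the same way under centring on ribosomal protein genes. For genes among the 8 highest and 8 lowest of each comparison, direction and call were kept in 1504 of 1508 alternative values, 4 lost the call (HSPA6 and HIST1H4B) and 0 turned. Called list members of the naming rule, 305 over all comparisons, kept both in 8221 of 8305, 84 lost the call (in 24 of the 305) and 0 turned. Of those in the text, IER5 lost it in the difference of enrichments under ribosomal protein centring and SNORA63 in Control Pulldown against Control Input in voom. TNIP2 lost its call in TNIP2 Pulldown against TNIP2 Input under quantile normalization and ribosomal protein centring. List results kept direction and call in 1355 of 1452, 83 lost the call, 1 gained it and 13 turned. These list values were all at the preset correlation and include the NF-kB lists, which the main setting did not call. The tally leaves out the test with an estimated correlation. Under that test, no list called in the 3 comparisons with TNIP2 Pulldown passed. Both counts of the difference of enrichments stayed within 1.5 times of 3301 and 2960 under every alternative except centring on ribosomal protein genes, from 2857 to 3834 higher and 2497 to 3411 lower over single libraries left out, and were 4235 and 3865 without both TNIP2 libraries numbered 3. Centring on ribosomal protein genes gave 1490 and 4952 there, 2437 genes higher in TNIP2 Pulldown against TNIP2 Input, 2966 higher in TNIP2 Pulldown against Control Pulldown, 6 lists in TNIP2 Input against Control Input, and TNIP2 at 1.55 in TNIP2 Pulldown against TNIP2 Input. It moved the median of all genes in the first 3 comparisons to -0.56, -0.47, -0.30 and, in TNIP2 Input against Control Input, to 0.23, and median centring to 0.14, 0.12 and 0.14 there. Quantile normalization gave TNIP2 1.10 in that comparison, r = 0.102 between both enrichments, 2 genes higher in Control Pulldown against Control Input, 5 lists in TNIP2 Input against Control Input, and a turned direction in the test of the ribosomal protein list, with medians relative to other genes of -0.0276 in Control Pulldown against Control Input, -0.190 in TNIP2 Pulldown against TNIP2 Input and -0.189 in the difference of enrichments. For Control Pulldown against Control Input, higher and lower counts of 0 and 20 became 4 and 44 on only the libraries compared, 25 and 111 with library weights, 2 and 40 without both TNIP2 libraries numbered 3, and 0 to 1 and 12 to 31 with single libraries left out; voom and a pseudocount of 5 each gave 1 higher. Genes lower with both constructs numbered 41, 71 and 36 under the first 3 of these and 11 to 30 with single libraries left out, and the lists called there rose from 7 to 12 on only the libraries compared and were 6 to 11 with single libraries left out. The correlation of enrichments was 0.0802 with a pseudocount of 5, 0.0327 with no filter, 0.101 with a stricter filter, 0.0867 on FPKM, 0.0272 without both TNIP2 libraries numbered 3 and 0.0366 to 0.0758 with single libraries left out. For TNIP2 Input against Control Input, library weights gave 1866 higher, 1755 lower and 7 lists, with the C/D snoRNA list at -0.108; the lists called, 11 in the main setting, were 5 with no filter, 6 after thinning and 5 to 11 with single libraries left out, and leaving out both TNIP2 libraries numbered 3 gave 2 lower. The glycolysis test there turned without TNIP2 Input replicate 3, with or without its Pulldown (median relative to other genes 0.00611; -0.156 to 0.00611 with single libraries left out). The direction of the test of NF-kB signalling components, not called in any setting, turned in TNIP2 Pulldown against Control Pulldown with median centring (median relative to other genes -0.0949) and without Control Pulldown replicate 3 or TNIP2 Pulldown replicate 2 (-0.154 to 0.0585 with single libraries left out). It turned in TNIP2 Pulldown against TNIP2 Input with median centring (-0.0806), no filter (0.0108), thinning (-0.0164) and without TNIP2 Pulldown replicate 2 (-0.139 without both TNIP2 libraries numbered 3, where it did not turn, and -0.117 to -0.00385 with single libraries left out). Unless a construction is named, the cause was not tested.

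With a replicate block on the extract, TNIP2 Pulldown against TNIP2 Input gave 4937 higher and 4670 lower, the difference of enrichments 4103 and 3654, and Control Pulldown against Control Input 2 and 26. This block also paired the tag-only libraries by number, which the check of deviations had not borne out. Neither block ended or turned a call of TNIP2, of a gene or list member of the naming rule or of a list. A block on the number over all groups gave 3523 and 3147 in the difference of enrichments, and not every library deviated most like the same number of the other group. The planned edgeR and DESeq2 fits were not run, because no column holds raw counts. Depth limits Control Pulldown most, where 3 reads equal 4.81 to 8.59 normalized counts.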

Other observations

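The test of snoRNAs against host genes was chosen before its result was seen. Tubulin and actin, DNA replication and oxidative phosphorylation genes held members called in both directions in the difference of enrichments, and these lists did not pass camera. Calls in both directions were common over all 14627 genes too, with 3301 higher and 2960 lower. Alpha-tubulin genes went opposite ways: TUBA1C had a difference of 2.36 and TUBA1B of -2.34, both with near-identical copies, and tubulin and actin genes had 3 of 18 higher and 2 lower (median 0.03). DNA replication genes had 11 of 31 higher and 3 lower (median 0.07), led by PCNA, the sliding clamp of DNA polymerases, which went from 4774 ± 729 to 28558 ± 3234 normalized counts with the TNIP2 fragment and from 4919 ± 424 to 4280.3 ± 63.5 with the tag alone (SD, n = 3), a difference of 2.78 (SE 0.21, adjusted p = 1.2e-06). In oxidative phosphorylation 21 of 76 genes were higher and 33 lower (median -0.50), with ATP5I at 3.17 and COX5A at -2.83. Glycolysis genes had 0 of 18 higher and 5 lower, or 1 lower adjusted over the list alone (median -0.62, adjusted p = 0.093), with TPI1 at -1.99. MIR3648, MIR663A and MIR3687 had the lowest differences of the microRNA list, -4.13, -4.31 and -4.60. Their reads may belong to longer transcripts that hold these sequences, so the values are uncertain and need not be of microRNAs. NORAD, listed as LINC00657, a cytoplasmic long non-coding RNA that sequesters Pumilio proteins, had a difference of 2.48 (SE 0.42, adjusted p = 3.1e-04), and MIAT had -3.44 (SE 0.65, adjusted p = 6.8e-04).

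The remaining lists did not pass camera in the difference of enrichments: box C/D snoRNA genes (21 higher and 11 lower of 85, median 0.22), box H/ACA snoRNA and scaRNA genes (13 higher and 12 lower of 66, median -0.32), the spliceosomal snRNA list with RNU86 included (0 higher and 0 lower of 6, median -1.16), snoRNA host genes (5 higher and 3 lower of 16, median 0.49), nucleus-retained long non-coding RNA genes (4 higher and 1 lower of 13, median -0.09), microRNA host genes (3 higher and 1 lower of 11, median 0.16) and microRNA genes (1 higher and 5 lower of 16, median -0.93). The same held for numbered zinc finger genes (102 higher and 65 lower of 452, median 0.04), endoplasmic reticulum chaperone and folding genes (4 higher and 6 lower of 30, median -0.06), cytosolic heat shock genes (8 higher and 3 lower of 18, median 0.79), interferon-stimulated genes (4 higher and 6 lower of 21, median -0.66), hnRNP and SR protein genes (11 higher and 5 lower of 32, median 0.20) and translation factor genes (12 higher and 13 lower of 37, median -0.18). Adjusted over the list alone, higher and lower counts were 98 and 63 for zinc fingers, 4 and 8 for interferon-stimulated genes, 12 and 5 for hnRNP and SR proteins and 12 and 14 for translation factors, and the same as over all genes for the other lists of this paragraph. Markers of other cells were mostly below the filter: blood cell markers (0 higher and 0 lower of 5, median 0.52), fibroblast and endothelial markers (1 higher and 1 lower of 5, median 0.60) and epithelial markers (0 higher and 0 lower of 4, median 0.07). In the nucleus-retained and translation factor lists the median was below 0, while the mean was 0.09 and 0.10 and the test pointed higher. By transcript length, the median difference was -0.25 in the shortest 10% of genes (median length 0.908 kb) and 0.50 in the longest 10% (9.09 kb), with Pearson r = 0.149 across genes. Of 13154 protein-coding genes 23.6% were higher and 20.9% lower, and of 660 lncRNA genes 11.1% and 14.8%.

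TNIP2 Input and Pulldown replicate 3 had scores of 54.7 and 47.8 on the second principal component, against -25.7 to 2.84 in the other 10 libraries. HSPA6 had 97 normalized counts in TNIP2 Input replicate 3 against 6 and 3 in replicates 1 and 2, and TNIP2 itself had 46568 against 16750 and 13318. FOSL1, an immediate early gene, had 28 against 8 and 8.

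All 8 snoRNAs tested that lie within SNHG1 had a higher difference, as did SNHG1 itself at 1.98. Among them SNORD30 and SNORD28 had differences of 3.74 and 2.86, and SNORA63 and its host EIF4A2 had 3.61 and 1.76. SNORA71A to SNORA71D had differences from -3.05 to -1.71, of which SNORA71A and SNORA71C were called lower, with SNHG17 at 0.72 (adjusted p = 0.17). Without a call of any of the snoRNAs, SNORD12, SNORD12B and SNORD12C had -0.05 (SE 0.66), -1.05 (SE 0.48) and -0.24 (SE 1.09) with ZFAS1 at 1.18, and SNORD45A, SNORD45B and SNORD45C had -0.26 (SE 0.52), 0.94 (SE 0.41) and -0.62 (SE 0.42) with RABGGTB at 1.91. Genes of this paragraph other than SNORD30 and SNORA63 were chosen after their values were seen. A hypothesis is that snoRNA reads in the purified material came with host transcripts. Of 151 snoRNA and scaRNA genes tested, 123 lie within a single other tested gene in the RefSeq table of GRCh38.p14, and over their 61 hosts the median difference of the snoRNAs correlated with that of the host across genes, which are not independent replicates, at Pearson r = 0.362 (Spearman rho = 0.348, permutation p = 0.0044 for the first, two-sided, 1 relation tested), above the 0.3 set beforehand. Medians over hosts were -0.07 for the snoRNAs and 0.60 for the hosts, and the sign was the same for 34 of 61 hosts, so a shared origin would cover a part of the snoRNAs at most. Hosts and snoRNAs share reads where the counting does not part them, so part of the correlation may arise from the counting.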
